A study of Mus musculus with 20 samples.

How the data were processed

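Poly-A RNA of subcutaneous HEPA1-6 tumors in C57/BL6 mice was sequenced, per the labels' protocols. HEPA1-6 is a mouse hepatoma line, and GSK343 is an inhibitor of EZH2, the histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2 (PRC2). Tumors received a control antibody or an antibody against the chemokine CXCL10, each with or without GSK343. The labels name 20 samples in 4 groups, and 19 have a column in the table used here: 4 libraries of control antibody (replicates 1, 2, 3 and 5), and 5 each of control antibody plus GSK343, anti-CXCL10, and anti-CXCL10 plus GSK343. Replicate 4 of control antibody was not analysed here. The series' design text speaks of 3 replicates per condition, whereas the sample labels number 5. The labels do not say which tumors came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

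The deposited values are FPKM (fragments normalized to gene length and to the mapped total) per gene. The unit was inferred from the values: the length-weighted column sums had a coefficient of variation of 0.691%, against 4.06% for the plain sums. The authors' steps before that are known only as names. Per the submitters' processing notes, Trimmomatic 0.33, TopHat2 2.1.0, HISAT2 2.1.0, HTSeq 0.6.0 and StringTie 1.3.3b were used, with builds GRCm38 and mm10, and neither the role of each tool nor the strand setting is given in the sources used here. Sequencing depth is unknown, because FPKM values carry no read totals and a search of the low values for whole-read steps found none. FPKM summed to between 533606 and 629679 per library. A fold change is therefore not accompanied by a counting error, and low values are the least certain.

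The deposited file held 14646 rows. Rows of the same gene ID were added together (8 IDs, 21 rows), which left 14633 genes. Each row had at least 1 FPKM in at least 4 libraries, so the deposited table looks already filtered on low values. Genes with 1 FPKM or more in at least 5 libraries were tested (14385), and 248 were removed. Of the gene IDs, 99.3% were found in the GENCODE M21 annotation of GRCm38, but only 70.0% of genes had the same start and end there; coordinates given here are those of the deposited table. Of the genes, 3494 overlap another listed gene, and how the authors assigned fragments shared by such genes, or by near-identical copies, is not given in the sources used here.

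The design fixed before the data were examined assumed a count table and named a test on log values as the one to use for FPKM; the latter was used, and settings that need counts were not run. Values were tested as log2(FPKM + 1) with limma 3.58.1 (R 4.3.3, statmod 1.5.0), with an intensity trend and robust empirical Bayes moderation, in a model of the 4 group means fitted to all 19 libraries. Changes on this scale are understated for low genes. Comparisons were 6: GSK343 with control antibody, GSK343 with anti-CXCL10, the average of these, their difference (the interaction), and anti-CXCL10 against control antibody without and with GSK343. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and an adjusted p for a gene below is from limma.

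Gene lists were also fixed before the data were examined: 46 lists with 1023 genes, of which 815 were measured (8 of them through the annotation's symbol), and 44 lists had at least 5 tested genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry (rotation test) as alternatives, adjusted over the 44 lists. With an estimated correlation, 0 of the 44 lists passed in each of the 6 comparisons, so the list calls depend on the preset value. A marker score of a library is the mean log2(FPKM + 1) of a list's genes.

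Genes named for a comparison are those past the threshold with the largest changes (10 per direction, at least 5 FPKM in the higher group), 11 key genes of the study's question, and up to 4 members of each list described, taken by p. Gene models without a given name, clone-based and accession-like names included, and pseudogenes and antigen receptor segments were left out of the first of these. Of the key genes 9 were in the table; Ncr1 and Klrb1c were not analysed here. Any other gene named was chosen after its values were seen, which is said beside it. Some genes that meet these rules are counted in the totals but not reported here.

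Alternatives fixed before the data were examined were another pseudocount, no filter or a stricter filter on low values, an added fold-change limit, a fit of the compared groups alone, the replicate number as a block, other list tests, and leaving out each library in turn. Added after seeing the data were median-ratio scaling, quantile normalization, skeletal muscle and keratinocyte marker scores as covariates, and a fit without the 3 libraries highest in skeletal muscle markers. Scores of single lists were compared by exact two-sided permutation tests. Sequences of abundant gene models were aligned with blastn to the mitochondrial genes of the reference, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

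The procedure was tested on simulated data with the 14385 genes of the real table, 200 of them changed, in 10 runs. For GSK343 with control antibody, 82.6% of genes changed by 1 on the log2 scale and 96.1% of those changed by 2 were recovered, with 4.69% false calls. For GSK343 with anti-CXCL10 these were 84.7%, 96.1% and 4.99%. A shifted list was found in 10 of 10 runs, and 1 of 390 unshifted lists was called. The simulated noise was independent between genes and the lists were random. These rates therefore do not cover genes that vary together, as in the real lists.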

Results

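Transcript levels were measured by poly-A RNA-seq in subcutaneous tumors of HEPA1-6, a mouse hepatoma line, grown in C57/BL6 mice. The groups were control antibody (n = 4 libraries), control antibody plus the EZH2 inhibitor GSK343 (n = 5), an antibody against the chemokine CXCL10 (n = 5), and that antibody plus GSK343 (n = 5). Values are the deposited FPKM of 14385 tested genes, sequencing depth is unknown, and no counting error can be given. Correlations between replicates ranged from 0.965 to 0.973 with control antibody, from 0.942 to 0.974 with control antibody plus GSK343, from 0.949 to 0.977 with anti-CXCL10 and from 0.963 to 0.976 with anti-CXCL10 plus GSK343. No pair of columns was identical. Means are given ± SD, log2 changes ± SE on the log2(FPKM + 1) scale, and adjusted p-values for genes are from limma.

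The design asks whether inhibition of EZH2 changes the transcripts of the tumor, and whether blocking CXCL10 alters that change. Among the genes of this question, Cxcl10 itself (ENSMUSG00000034855, minus strand of chromosome 5, 92346638 to 92348889, build GRCm38), a T cell-attracting chemokine induced by interferon, had 96.9 ± 24.5 FPKM with control antibody (n = 4) and 205 ± 66.1 with GSK343 added (n = 5). Cxcl10 rose by 1.05 ± 0.27 (95% interval 0.48 to 1.61, adjusted p = 0.0299), with all 5 treated libraries above the highest control; groups without overlap, in either direction, arise by chance for 1.59% of genes. The related chemokine Cxcl9 rose from 60.5 ± 21.8 to 161 ± 63.9 FPKM (1.35 ± 0.34, adjusted p = 0.026, 4 of 5 treated libraries above the highest control). Ifng, the gene of interferon-gamma, rose from 2.61 ± 0.673 to 10.6 ± 7.16 FPKM (1.52 ± 0.30, adjusted p = 0.00756, 5 of 5). Prf1, which encodes perforin, rose by 1.51 ± 0.36 (adjusted p = 0.0201, 3 of 5), and Gzmb, which encodes granzyme B, by 1.19 ± 0.31 (adjusted p = 0.0326, 4 of 5). Cxcl11 (1.29 ± 0.43, adjusted p = 0.0964) and Cxcr3, the receptor of these chemokines (0.73 ± 0.24, adjusted p = 0.0897), did not pass, although 4 of 5 treated libraries lay above the control mean for each. The target of the drug, Ezh2 (chromosome 6, 47530274 to 47595341), had 29.7 ± 3.24 and 25.3 ± 3.17 FPKM, a difference of -0.22 ± 0.10 that did not pass (adjusted p = 0.244), and Hdac10 differed by -0.12 ± 0.17 (adjusted p = 0.779). Cxcl10 and Cxcl11 overlap Art3 in the annotation, so fragments of these genes could be shared. The Cxcl10 call was lost without replicate 1 (adjusted p = 0.119) or 5 (0.0962) of control antibody, or replicate 2 (0.0795) or 3 (0.0875) of the treated group, and the Cxcl9 call without the same libraries (0.1, 0.0911, 0.0666 and 0.0798) or treated replicate 4 (0.0527). Without replicates 1, 2 and 5 of control antibody and treated replicates 2 and 3, adjusted p was 0.11, 0.0742, 0.0977, 0.0773 and 0.0875 for Gzmb, which also lost its call without treated replicate 5 (0.0649), and 0.0746, 0.0536, 0.0625, 0.0521 and 0.0569 for Prf1. Cxcr3 passed without treated replicate 1 (adjusted p = 0.00131).

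**Figure D1:**
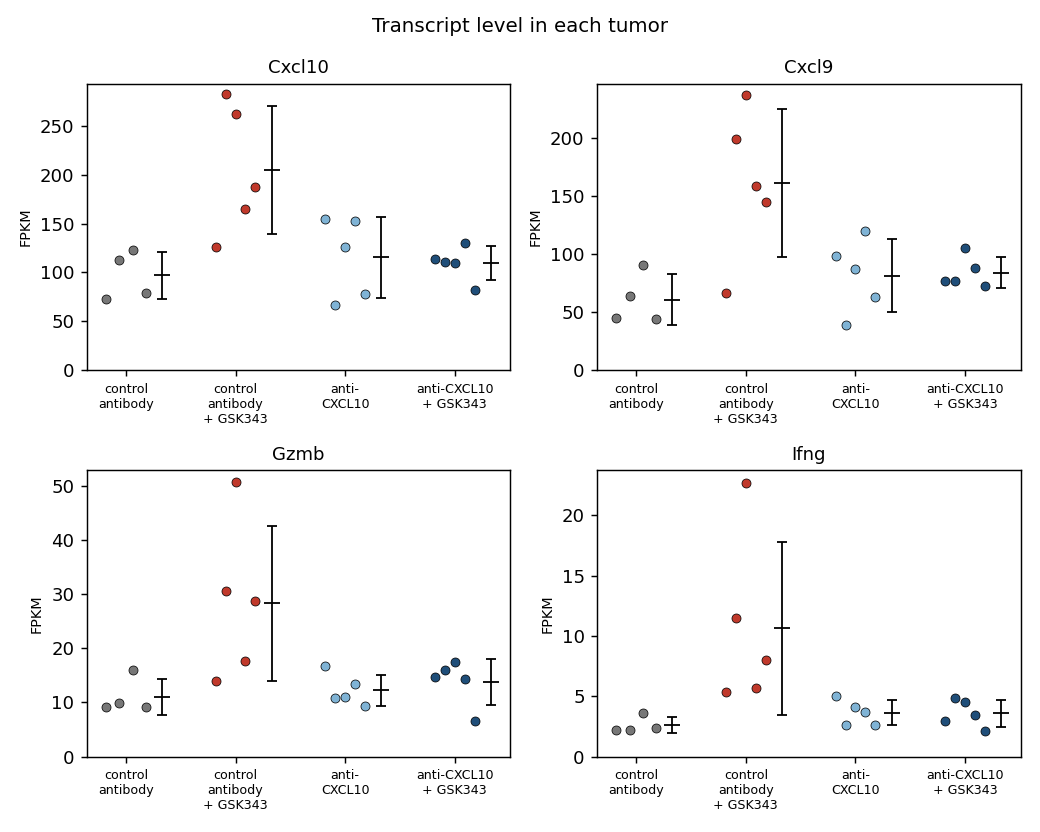
FPKM of Cxcl10, Cxcl9, Gzmb and Ifng in each tumor library (points) of the 4 groups, with the mean and SD of each group beside the points. Mean Cxcl10 was 205 FPKM in control antibody plus GSK343 and between 96.9 and 116 in the other groups.

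Markers of immune cells were among the genes that rose with GSK343 under control antibody. T cell markers had 15 of 20 genes past the threshold (19 when adjusted over the list alone) and a median change of 0.97, with Cd2 (1.25 ± 0.22), Cd3e (1.19 ± 0.21) and the T cell receptor kinase Lck (1.19 ± 0.21) among them. Cytotoxic effectors rose in 11 of 16 (15 adjusted over the list alone, median 1.17), and NK cell markers in 9 of 13 (10 adjusted over the list alone, median 1.11), including the receptors Klre1 (1.39 ± 0.20) and Klrd1 (1.51 ± 0.27). The immune checkpoint list, inhibitory receptors and their ligands, had 6 of 11 (10 adjusted over the list alone), among them Lag3 (1.19), Havcr2 (0.84) and Tigit (0.72). Regulatory T cell markers had 4 of 5 (5 adjusted over the list alone, median 0.90), and macrophage markers 13 of 23 higher (16 higher and 2 lower adjusted over the list alone, median 0.81), with the complement gene C1qc at 1.05 and Ms4a7 at 1.10. Of 18 listed B and plasma cell markers only 7 were in the deposited table and 6 were tested, so the rest were not assessed. Of the 6, 4 rose (5 adjusted over the list alone, median 2.11), led by the immunoglobulin genes Igkc (3.87 ± 1.02) and Ighm (2.89 ± 0.77). The plasma cell chaperone Mzb1 rose by 1.33. Adjusted p was 0.072 with an estimated correlation for T cell, cytotoxic, NK cell, checkpoint, macrophage and B and plasma cell lists, and adjusted p = 0.0867 with an estimated correlation for regulatory T cells. Mean T cell marker scores were 2.62 ± 0.220 with control antibody and 3.55 ± 0.458 with GSK343 added. All 5 treated libraries lay above the highest control (2.78), the lowest being replicate 1 at 2.91. The exact permutation test of this score gave p = 0.0159, and 0.063 when adjusted over the 45 lists scored. No list's score passed that adjusted test in this comparison. In the same comparison the skeletal muscle score was 1.85 ± 0.507 and 4.04 ± 1.81, and treated replicates 4, 3 and 5 had the highest muscle scores of all libraries (6.50, 4.64 and 4.55).

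Interferon-induced genes and antigen presentation rose beside them. The interferon-gamma response list had 23 of 31 genes higher (29 adjusted over the list alone, median 0.91), among them the GTPases Gbp7 (0.92) and Gbp5 (1.05) and the protease inhibitor Serpina3g (1.49). Of the type I interferon response 15 of 34 rose (25 adjusted over the list alone, median 0.73), with Ifit1 at 1.01, Parp14 at 0.88 and the nucleic acid sensor Zbp1 at 1.06. Adjusted p was 0.0867 with an estimated correlation for both lists. Chemokines had 14 of 32 higher (20 higher and 2 lower adjusted over the list alone, median 0.92, adjusted p = 0.072 with an estimated correlation), including Ccl6 (1.68 ± 0.25), Ccl4 (1.56 ± 0.28), Ccl5 (1.48 ± 0.30) and Xcl1 (1.22). MHC class I presentation rose in 9 of 23 (20 adjusted over the list alone, median 0.54, adjusted p = 0.10 with an estimated correlation), with the peptide transporter subunit Tap2 at 0.71 and Tapbp at 0.65. For MHC class II presentation 9 of 12 rose (11 adjusted over the list alone, median 0.86, adjusted p = 0.0883 with an estimated correlation), with the protease Ctss at 1.54. Dendritic cell markers had 3 of 12 higher (8 higher and 1 lower adjusted over the list alone, median 0.60, adjusted p = 0.0867 with an estimated correlation), and neutrophil markers 3 of 15 (6 adjusted over the list alone, median 0.48, adjusted p = 0.271 with an estimated correlation). The muscle score difference stated for the T cell markers holds for these lists too, as the libraries are the same.

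Of the genes named for the size of their change, the largest increase was that of Igj, the joining chain of secreted IgA and IgM, from 4.87 to 44.4 FPKM (3.46 ± 0.63, adjusted p = 0.00478). It was followed by Pvalb, a calcium buffer of fast muscle fibers (3.01 ± 0.84, adjusted p = 0.0437), and by the stress-induced chaperones Hspa1b (2.48 ± 0.56, adjusted p = 0.0163) and Hspa1a (2.41 ± 0.55, adjusted p = 0.0159), which are near-identical copies whose split is uncertain. Nos2, the inducible nitric oxide synthase of activated macrophages, rose from 2.92 to 17.5 FPKM (2.11 ± 0.48, adjusted p = 0.0152), and Slamf7, a receptor of NK and plasma cells, from 1.13 to 6.45 FPKM (1.83 ± 0.31, adjusted p = 0.00336). Ly6i (1.86 ± 0.35), Clec3b (1.79), Retnlg (1.78 ± 0.42) and Arf2 (1.76) completed the 10. All 5 treated libraries lay above the control mean for each of these 10 genes. Of 35 hepatocyte and hepatoma genes, 5 fell (adjusted over the list alone 18 lower and 1 higher, median -0.51, adjusted p = 0.12 with an estimated correlation), among them the pioneer transcription factor Foxa1 (-0.65 ± 0.12) and the transferrin gene Trf (-0.70). Among the largest decreases were Serpina6, corticosteroid-binding globulin, from 73.3 to 15.9 FPKM (-2.29 ± 0.62, adjusted p = 0.0392), Ttr, the thyroid hormone carrier transthyretin, from 141 to 41.6 FPKM (-1.67 ± 0.46, adjusted p = 0.0398), and Serpind1, heparin cofactor II, from 42.2 to 14.3 FPKM (-1.48 ± 0.26, adjusted p = 0.00412). Akr1c6 (-1.94), Casp2 (-1.65), Eps8 (-1.64), Ces2e (-1.56), Krt23 (-1.56) and Diablo (-1.49 ± 0.33) also fell. All 5 treated libraries lay below the control mean for each of these 9 except Casp2 (4 of 5). Xenobiotic metabolism fell in 2 of 23 genes (4 adjusted over the list alone, median -0.36, adjusted p = 0.223 with an estimated correlation), with Abcc2 at -0.85 and Gsta4 at -1.12.

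The lists tied to the drug's target did not pass in this comparison. Of 10 PRC2 subunits 0 passed the limma test (0 adjusted over the list alone, median -0.05, camera adjusted p = 0.873). Of 79 listed transcription factors known as Polycomb targets, only 17 were in the deposited table and 16 were tested, so the rest were not assessed. Among the 16, Hoxc6 rose (0.83) and Tbx3 fell (-0.55), with 5 higher and 3 lower adjusted over the list alone (median 0.23, camera adjusted p = 0.193). Mitotic genes had a median of 0.02 and DNA replication genes of -0.03, with 0 of 27 and 0 of 26 past the threshold. Fibroblast and matrix genes had 0 of 28 past the threshold (0 adjusted over the list alone, median 0.36), although camera called the list; adjusted p = 0.394 with an estimated correlation. Skeletal muscle markers had 1 of 18 past the threshold (15 adjusted over the list alone, median 2.37, adjusted p = 0.243 with an estimated correlation), and the muscle actin Acta1 had 13.7 ± 6.97 FPKM with control antibody and 197 ± 273 with GSK343 added. The immediate early genes, among them Jun (0.97) and Klf2 (1.18), rose in 3 of 16 (8 adjusted over the list alone, median 0.43, adjusted p = 0.259 with an estimated correlation). Heat shock genes rose in 3 of 15 (5 adjusted over the list alone, median 0.15, adjusted p = 0.271 with an estimated correlation), Hspb1 by 1.73 ± 0.39.

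In all, 787 of 14385 genes passed in this comparison, 627 higher and 160 lower, of which 212 and 17 changed at least 2-fold. Median-ratio scaling gave 726 higher and 105 lower, and quantile normalization 630 and 215. Of the 787, 743 were protein coding, and 14 were immunoglobulin or T cell receptor segments, all higher. Camera called 25 of the 44 lists (22 up, 3 down), and fry 19. The number of genes was 299 without replicate 1 and 319 without replicate 5 of control antibody, and 1389, 453 and 375 without treated replicates 1, 2 and 3. Without the 3 libraries highest in skeletal muscle markers, which leaves 2 treated libraries, 15 genes passed, with Cxcl10 at 0.99 ± 0.36 (adjusted p = 0.237) and Cxcl9 at 0.98 ± 0.44 (adjusted p = 0.333). With muscle and keratinocyte scores as covariates 3 genes passed, with Cxcl10 at 0.72 ± 0.30 (adjusted p = 0.376) and Cxcl9 at 0.79 ± 0.35 (adjusted p = 0.406). In these fits adjusted p was 0.0728 and 0.173 for Ifng (1.32 ± 0.29 and 1.36 ± 0.38), 0.274 and 0.327 for Gzmb (0.891 ± 0.354 and 0.996 ± 0.389), and 0.148 and 0.256 for Prf1 (1.23 ± 0.37 and 1.35 ± 0.45). A fit of the compared groups alone called 233 genes, with Cxcl10 (adjusted p = 0.0744), Cxcl9 (0.0902), Ifng (0.0679), Gzmb (0.106) and Prf1 (0.104) no longer past the threshold. Of the 25 largest-change and key genes that passed, Diablo, Ifng, Igj, Ly6i, Serpind1 and Slamf7 did so in each of the 19 fits that left out 1 library, and the other 19 lost the call in at least 1.

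**Figure D2:**
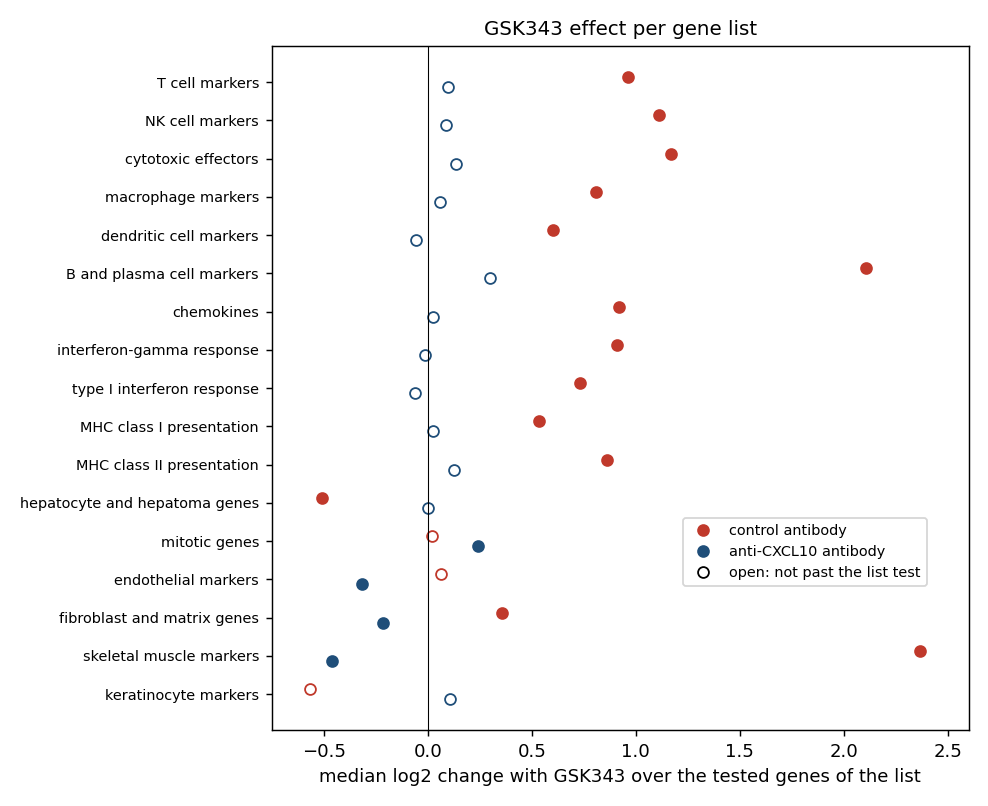
Median log2 change with GSK343 over the tested genes of each gene list, under control antibody and under anti-CXCL10; filled points mark lists past camera's preset-correlation test and open points those that were not. T cell markers had a median change of 0.97 under control antibody and 0.10 under anti-CXCL10.

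With anti-CXCL10 present, the same genes differed little between tumors with and without GSK343. Cxcl10 had 116 ± 41.5 FPKM without the drug (n = 5) and 110 ± 17.4 with it (n = 5), a change of -0.01 ± 0.25 with a 95% interval of -0.55 to 0.52, and 1 of 5 treated libraries above the mean of the untreated. For Cxcl9 the change was 0.13 ± 0.32 (-0.54 to 0.80), with 81.3 ± 31.6 and 83.7 ± 13.1 FPKM. Ifng (-0.02), Prf1 (0.04), Gzmb (0.12), Cxcl11 (0.15), Cxcr3 (0.00), Ezh2 (0.11) and Hdac10 (-0.34) likewise did not pass; the adjusted p was 1 for each of the 9 genes. T cell markers had a median of 0.10 (camera adjusted p = 0.13), and the medians of the interferon-gamma response (-0.01) and chemokines (0.03) did not pass either. Camera called 12 lists whose genes all missed the threshold: 4 up, mitotic genes (median 0.24), DNA replication genes (0.14), cholesterol biosynthesis (0.17) and neutrophil markers (0.22), and 8 down, including endothelial markers (-0.32), immediate early genes (-0.21), fibroblast and matrix genes (-0.21) and skeletal muscle markers (-0.46). In each of these lists 0 genes passed when adjusted over the list alone. The calls were lost with an estimated correlation: adjusted p = 0.216 for mitotic, 0.176 for DNA replication, 0.217 for cholesterol, 0.701 for neutrophil, 0.176 for endothelial, 0.384 for immediate early, 0.651 for fibroblast and 0.894 for muscle lists. Fry called 0.

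Of the 14385 genes 0 passed limma's test in this comparison, with 418 at an unadjusted p under 0.05, where 719.25 would be expected by chance, and a smallest adjusted p of 0.531. Without replicate 1 of anti-CXCL10, 1 gene passed, and camera called 7 lists without replicate 3 of anti-CXCL10 plus GSK343. No other setting tried called a gene, the fit without the libraries highest in muscle markers included. A miss of the threshold does not show that the groups were alike, and the intervals of Cxcl10 and Cxcl9 give the changes that the data allow.

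The difference between the GSK343 effects under the antibodies was tested as an interaction, and 9 genes passed, all with a smaller change under anti-CXCL10. Ccl6, a myeloid chemokine, had 74.4 FPKM with control antibody and 241 with GSK343 added, against 83.1 and 68.5 with anti-CXCL10, an interaction of -1.92 ± 0.34 (adjusted p = 0.0489). Ly9 (2.40 and 7.26 against 2.93 and 2.52 FPKM, -1.43 ± 0.22, adjusted p = 0.0252) and Cd48 (8.02 and 20.6 against 8.86 and 9.88 FPKM, -1.10 ± 0.19, adjusted p = 0.0404) encode receptors of the SLAM family of lymphocyte and myeloid cells. The others named by rule were Trpv2, a cation channel (-1.67 ± 0.27, adjusted p = 0.0273), Alox5ap, the activating protein of leukotriene synthesis (-1.38 ± 0.24, adjusted p = 0.0459), and Themis2, an adaptor of B cells and macrophages (-0.97 ± 0.15, adjusted p = 0.0252). Under control antibody all 5 treated libraries lay above the highest control for these 6 genes. Ly9 overlaps Cd244 in the annotation, so its fragments could be shared. The key genes did not pass: Cxcl10 differed by -1.06 ± 0.37 (95% interval -1.84 to -0.28, adjusted p = 0.222), Cxcl9 by -1.22 ± 0.46 (adjusted p = 0.258), Ifng by -1.54 ± 0.42 (adjusted p = 0.131), Prf1 by -1.46 ± 0.49 (adjusted p = 0.204) and Gzmb by -1.07 ± 0.43 (adjusted p = 0.282). Cxcl9 and Cxcr3 passed without replicate 1 of control antibody plus GSK343 (adjusted p = 0.0444 and 0.0278).

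By lists, 16 of 20 T cell markers and 24 of 31 interferon-gamma response genes were lower in the interaction when adjusted over the list alone, against 0 of each over all genes (median interactions -0.96 and -0.98, adjusted p = 0.119 with an estimated correlation for both). Of the macrophage markers 16 were lower and 1 higher adjusted over the list alone, and of 32 chemokines 15, with Ccl6 also past the threshold over all genes. Camera called 29 lists (7 up, 22 down) and fry 13; the smallest adjusted p was 0.119 with an estimated correlation. Skeletal muscle markers had a median interaction of -2.80 (adjusted p = 0.201 with an estimated correlation), so muscle transcripts moved with the same groups.

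The count of 9 depended on single libraries. It was 1, 4, 47 and 0 without control antibody replicates 1, 2, 3 and 5. It became 476, 0, 5 and 5 without control antibody plus GSK343 replicates 1, 2, 3 and 4, and 5, 0, 1 and 57 without anti-CXCL10 replicates 1, 3, 4 and 5. Leaving out replicates 1, 2, 4 and 5 of anti-CXCL10 plus GSK343 gave 0, 5, 3 and 0. It was 1 without the 3 libraries highest in muscle markers and 0 with muscle and keratinocyte scores as covariates, and none of the 6 genes named here passed in each of the 19 fits that left out 1 library. Across the 787 genes past the threshold under either antibody, the GSK343 changes under the antibodies correlated at r = 0.205 (rho = 0.185), with the same sign for 58.8%; over all 14385 genes r was 0.019 with 50.2%. These are correlations across genes, which are not independent replicates, and the 787 were selected by their change under control antibody. The r of 0.205 became -0.013, 0.334, 0.359 and -0.030 without replicates 2, 3, 4 and 5 of anti-CXCL10, and 0.068 without replicate 3 of anti-CXCL10 plus GSK343.

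**Figure D3:**
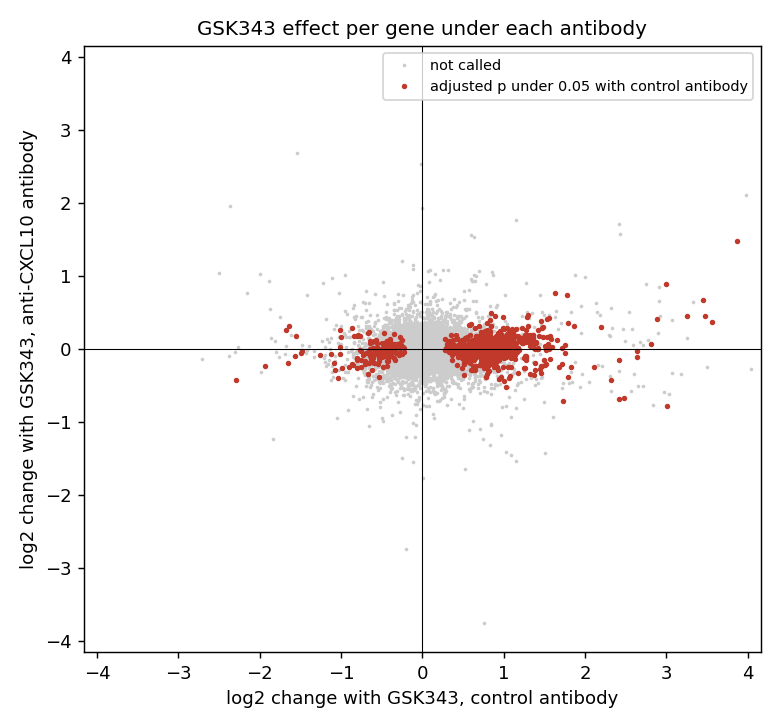
Log2 change with GSK343 of each of 14385 tested genes under control antibody (horizontal axis) and under anti-CXCL10 (vertical axis); red points are the 787 genes past an adjusted p of 0.05 under control antibody. The red points spread along the horizontal axis, with r = 0.205 between the axes.

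Averaged over both antibodies, GSK343 raised 117 genes and lowered 18. Of the genes named by size, Igj changed most (2.06 ± 0.43, adjusted p = 0.0416), followed by Retnlg (1.26) and Ly6i (1.09). Ccl4 (0.99 ± 0.19, adjusted p = 0.0314) and Ccl3 (0.86), chemokines that attract T cells and macrophages, the phosphatase of T cell receptor signaling Ptpn22 (0.98 ± 0.16, adjusted p = 0.0197), the inhibitory myeloid receptor Clec12a (0.88 ± 0.14, adjusted p = 0.0197) and the activation marker Cd69 (0.86) also rose, as did Slfn4 (0.92) and Fam26f (0.81). Retnlg, Ptpn22, Ccl3 and Cd69 were above the untreated mean in 5 of 5 treated libraries under each antibody. Under control antibody and anti-CXCL10 this held for 5 and 4 libraries with Igj, Ly6i, Ccl4 and Slfn4, for 5 and 3 with Clec12a, and for 5 and 2 with Fam26f. The lower genes changed less: Lrrc47 (-0.64), Esm1 (-0.57), an endothelial proteoglycan that overlaps Gzmk in the annotation, Fgf1 (-0.51), Slc44a3 (-0.46), the corepressor Tle1 (-0.46), Lbp (-0.39), Rtn4rl1 (-0.38), Tbx3, Galnt18 and S1pr1 (-0.37). Cxcl10 (0.52 ± 0.19, adjusted p = 0.229), Cxcl9 (0.74 ± 0.23, adjusted p = 0.159) and Ifng (0.75 ± 0.21, adjusted p = 0.101) did not pass, although Cxcl9 and Cxcr3 passed without replicate 1 of control antibody plus GSK343 (adjusted p = 0.0189 and 0.0206).

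T cell markers had 5 of 20 genes higher on average (18 adjusted over the list alone, median 0.53) and NK cell markers 4 of 13 (9 adjusted over the list alone, median 0.64), each with adjusted p = 0.0797 with an estimated correlation. MHC class II presentation had 3 of 12 (10 adjusted over the list alone, median 0.49, adjusted p = 0.105 with an estimated correlation). Of the interferon-gamma response 0 of 31 passed over all genes and 25 when adjusted over the list alone (median 0.41, adjusted p = 0.142 with an estimated correlation). The hepatocyte and hepatoma list had 0 past the threshold and 4 lower adjusted over the list alone (median -0.30, adjusted p = 0.166 with an estimated correlation). Camera called 26 lists (21 up, 5 down) and fry 16. The skeletal muscle score changed by 2.19 with GSK343 under control antibody and by -0.43 under anti-CXCL10, so muscle also enters the average. The average mixes an effect seen under control antibody with 1 not detected under anti-CXCL10, and the interaction above bears on it.

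The average count of 135 also moved with single libraries. It was 7, 63 and 14 without control antibody replicates 1, 2 and 5, and 556, 14, 21, 21 and 24 without control antibody plus GSK343 replicates 1 to 5. Without anti-CXCL10 replicates 1, 2, 4 and 5 it was 30, 5, 212 and 9, and without anti-CXCL10 plus GSK343 replicates 1 to 4 it was 55, 9, 7 and 12. Without the 3 libraries highest in muscle markers 2 genes passed, and 0 with muscle and keratinocyte scores as covariates. Clec12a was the only gene of the 20 named here that passed in each of the 19 fits that left out 1 library.

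Anti-CXCL10 and control antibody were compared first without GSK343. Cav1, which encodes caveolin of the plasma membrane's caveolae, had 11.3 FPKM with control antibody (n = 4) and 3.40 with anti-CXCL10 (n = 5). The change was -1.49 ± 0.23 (adjusted p = 0.0244). All 5 anti-CXCL10 libraries lay below the lowest control. Cav1 was picked by its test in these same libraries, so that separation is not further evidence. Cxcl10 transcripts differed by 0.20 ± 0.27 (adjusted p = 0.881), Cxcl9 by 0.38 ± 0.34 (adjusted p = 0.83), Ifng by 0.35 (adjusted p = 0.828) and Ezh2 by -0.24 ± 0.10 (adjusted p = 0.70), with 3, 4, 5 and 0 of the 5 libraries above the control mean. The interferon-gamma response was called up by camera (median 0.32) and the cholesterol biosynthesis (-0.23), DNA replication (-0.15), mitotic (-0.09), keratinocyte (-0.91) and histone (-0.20) lists down, with 0 genes of each past the threshold; adjusted over the list alone, 1 cholesterol gene was lower and 0 genes of the other lists passed. For each of these 6 lists adjusted p = 0.851 with an estimated correlation, and fry called 0 of the 44 lists, so the direction of these lists rests on the preset correlation.

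By limma 2 genes passed in this comparison, Cav1 and Gm28062 (-1.02), the latter named after its values were seen, and 979 genes had an unadjusted p under 0.05. No gene passed without control antibody replicate 2 or 5, or without anti-CXCL10 replicate 2, 3 or 4 (0 each), 1 passed without control antibody replicate 3, and 0 passed without the 3 libraries highest in muscle markers or with muscle and keratinocyte scores as covariates. The Cav1 call was lost without control antibody replicates 2 (adjusted p = 0.204), 3 (0.0604) and 5 (0.2), and without anti-CXCL10 replicates 1 (0.0767), 2 (0.12), 3 (0.115) and 4 (0.0728), as well as in a fit of the compared groups alone (0.211). Camera called 11, 14, 15 and 10 lists without control antibody replicates 2 and 3 and anti-CXCL10 replicates 2 and 5. Sample index numbers run over 10 values in the control-antibody libraries and over the same 10 in the anti-CXCL10 libraries, which would arise if the antibodies were sequenced in separate batches. Each such batch would hold only 1 antibody, so no value within a batch can be had for either antibody comparison, and without GSK343 antibody and batch cannot be told apart.

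With GSK343 present, anti-CXCL10 tumors were compared with control antibody tumors. Igj fell from 44.4 to 1.86 FPKM (-4.10 ± 0.59, adjusted p = 0.0014). Ifng fell by 1.19 ± 0.29 (adjusted p = 0.015) and Cxcl10 by 0.85 ± 0.25 (adjusted p = 0.0411), with 5 and 4 of the 5 anti-CXCL10 libraries below the lowest control antibody library. The order of Cxcl9 (-0.83 ± 0.32, adjusted p = 0.106), Gzmb (-0.92, adjusted p = 0.0557), Cxcr3 (-0.62, adjusted p = 0.0896), Cxcl11 (-1.15, adjusted p = 0.0827) and Prf1 (-0.84, adjusted p = 0.125) was the same, 5 of 5 libraries lying below the mean, but these did not pass. Ezh2 differed by 0.10 (adjusted p = 0.574). The call of Cxcl10 was lost without control antibody plus GSK343 replicates 2 (adjusted p = 0.104), 3 (0.103) and 5 (0.0644), and without anti-CXCL10 plus GSK343 replicates 1 (0.0663), 2 (0.0671), 3 (0.07) and 5 (0.107). Cxcl9 and Cxcr3 passed without control antibody plus GSK343 replicate 1 (adjusted p = 0.0134 and 0.00181).

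Chemokines were lower in 15 of 32 genes (23 lower and 2 higher adjusted over the list alone, median -0.90, adjusted p = 0.155 with an estimated correlation), with Ccl6 at -1.80 ± 0.23 and Ccl7 at -1.76. T cell markers were lower in 14 of 20 (17 adjusted over the list alone, median -0.74), including Cd2 (-1.09) and Lck (-1.02), the type I interferon response in 17 of 34 (26 adjusted over the list alone, median -0.69), including Ifit1 (-0.95), and NK cell markers in 8 of 13 (11 adjusted over the list alone, median -0.83), including Klre1 (-0.94); for these 3 lists adjusted p = 0.159 with an estimated correlation. Macrophage markers had 14 lower and 1 higher of 23 (17 and 1 adjusted over the list alone, median -0.75, adjusted p = 0.159 with an estimated correlation), the higher gene being Spp1, osteopontin (0.56). The interferon-gamma response was lower in 10 of 31 (23 adjusted over the list alone, median -0.65, adjusted p = 0.216 with an estimated correlation). Fibroblast and matrix genes were lower in 14 of 28 (21 adjusted over the list alone, median -0.75, adjusted p = 0.162 with an estimated correlation), among them the matrix proteins Mfap5 (-1.44), Fbln2 (-1.19), Lum (-1.85) and the collagen chain Col1a2 (-1.01). Immediate early genes were lower in 11 of 16 (13 adjusted over the list alone, median -0.79, adjusted p = 0.159 with an estimated correlation), with Atf3 at -1.44, Zfp36 at -1.23 and Nr4a1 at -0.83. Skeletal muscle markers had 1 of 18 lower (16 adjusted over the list alone, median -2.41, adjusted p = 0.254 with an estimated correlation), in the same direction as the immune lists. By exact permutation tests of the scores, adjusted p over 45 lists was 0.0357 for chemokines and macrophage markers. It was 0.0564 for T cell markers, 0.0621 for NK cell markers and the interferon-gamma response, and 0.0893 for skeletal muscle markers.

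Of 79 listed Polycomb target transcription factors, 16 were tested. As a list they did not pass camera's test for GSK343 under control antibody, although Hoxc6 and Tbx3 passed there as single genes. Between the antibodies with GSK343, 6 of the 16 were lower and 1 higher (8 and 1 adjusted over the list alone, median -0.26, adjusted p = 0.155 with an estimated correlation). Tbx15 (-0.95), Hoxd8 (-0.80), Gata3 (-0.73), a transcription factor also of T cells, and Hoxc8 (-0.66) were lower, and Tbx3 (0.39) higher. Hepatocyte and hepatoma genes were higher in 8 of 35, and H19, a fetal liver transcript, was lower (-1.27); adjusted over the list alone 19 were higher and 1 lower (median 0.49, adjusted p = 0.216 with an estimated correlation). They included Foxa1 (0.58), the plasma protein gene Itih2 (0.65) and albumin, Alb (0.52). Single genes with large increases were the ribosomal protein gene Rps15a (1.80 ± 0.54, adjusted p = 0.0442), which has near-identical copies and is uncertain, Eps8 (1.54), the glutathione transferase Gsta3 (1.51 ± 0.38, adjusted p = 0.0189), Diablo (1.38), Serpind1 (1.37 ± 0.24, adjusted p = 0.00303), Fmo2 (1.32), Pip5k1a (1.27) and the apolipoprotein Apoa1 (1.16 ± 0.32, adjusted p = 0.0317). Each was above the mean of control antibody plus GSK343 in 5 of 5 libraries. Lower were Pvalb (-3.07), Chil3, a secreted protein of alternatively activated macrophages (-2.70 ± 0.84, adjusted p = 0.0485), Clec3b (-2.35), the AP-1 subunit Fosb (-2.17 ± 0.43, adjusted p = 0.00578), the matrix gene Ogn (-2.15 ± 0.35, adjusted p = 0.00224), the eosinophil chemokine Ccl11 (-2.08 ± 0.45, adjusted p = 0.00814), Dpt (-2.07), Car4 (-2.04) and Nos2 (-1.96 ± 0.45, adjusted p = 0.0117), each below that mean in 5 of 5.

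With GSK343, 1456 genes passed between the antibodies, 501 higher (34.4%) and 955 lower; 17 and 202 changed at least 2-fold. Median-ratio scaling gave 316 higher (22.2%) and 1108 lower, and quantile normalization 701 higher (43.5%) and 910 lower. Camera called 26 lists (2 up, 24 down) and fry 27. The count was 932 and 861 without control antibody plus GSK343 replicates 2 and 3, and 963 and 837 without anti-CXCL10 plus GSK343 replicates 1 and 5. Without the 3 libraries highest in muscle markers 497 genes passed, with Cxcl10 at -0.80 ± 0.35 (adjusted p = 0.202), and with muscle and keratinocyte scores as covariates 9 genes passed, with Cxcl10 at -0.46 ± 0.30 (adjusted p = 0.465). Of the 497, 301 were among the 1456, and 229 were higher and 268 lower. Ifng lost its call in both (-0.988 ± 0.285, adjusted p = 0.0667, and -0.995 ± 0.381, 0.212) and in a fit of the compared groups alone (-1.19 ± 0.34, 0.062). Of the 22 largest-change and key genes that passed, 12 did so in each of the 19 fits that left out 1 library, among them Igj, Ifng, Serpind1, Ogn, Fosb, Ccl11 and Nos2.

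Of the genes raised by GSK343 under control antibody, 503 were lower with anti-CXCL10 plus GSK343 than with control antibody plus GSK343, and of those lowered, 114 were higher; 0 genes passed in the same direction in both. Both comparisons use the libraries of control antibody plus GSK343. Independent lists of these lengths would share 41.6 and 5.57 genes. In 50 simulations without any effect the overlap was 0. Without effects hardly any gene can pass in either comparison, so that 0 was set in advance. It does not measure the overlap that the shared libraries create. Across genes the changes correlated at r = -0.799 (covariance -0.119), against r = -0.468 (covariance -0.0242) in the simulations, and with the shared libraries split between the comparisons r averaged -0.510 (-0.636 to -0.310 over 10 splits, covariance -0.0903). The simulated values leave out real effects and any correlation between genes, and the independent ones leave out the shared libraries.

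**Figure D4:**
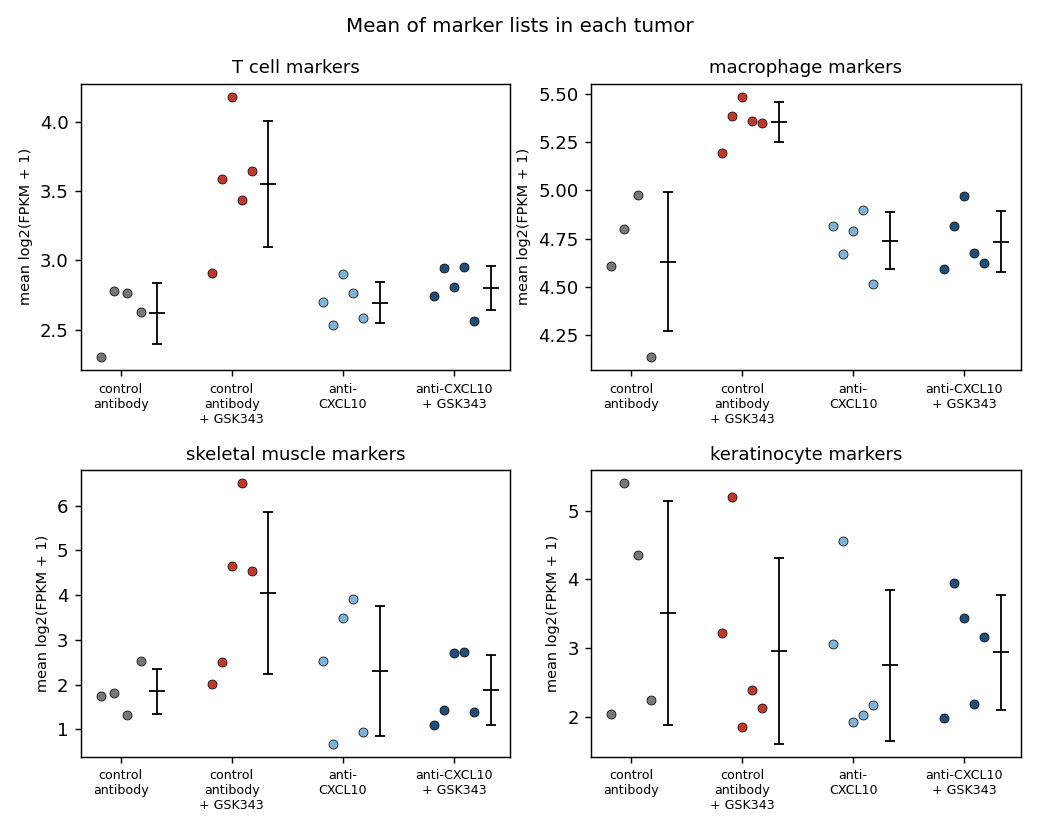
Mean log2(FPKM + 1) of T cell, macrophage, skeletal muscle and keratinocyte markers in each tumor library (points), with the mean and SD of each group beside the points. Mean T cell scores were 2.62 and 3.55 with control antibody without and with GSK343, and 2.69 and 2.80 with anti-CXCL10, and the muscle scores of control antibody plus GSK343 spread up to 6.50.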

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

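The tests of tumor cell share, skeletal muscle, an antibody batch and Y-linked transcripts, and the added scaling and covariate settings, were chosen after the results they bear on were seen, whereas the regroupings of libraries were planned.

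The difference between the GSK343 effects under the antibodies drew attention first, because the test of the difference itself passed for 9 genes. These were Ly9 (-1.43), Cd48 (-1.10), Trpv2 (-1.67), Ccl6 (-1.92), Themis2 (-0.97), Alox5ap (-1.38) and, outside the naming rule and chosen after their values were seen, Dock2 (-0.96), a guanine exchange factor of leukocyte migration, and the gene models AB124611 (-1.71) and AI662270 (-1.04). Negative values mean a smaller change with GSK343 under anti-CXCL10. Among the lists past camera's interaction test, the immune ones had negative medians: NK cells (-0.94), T cells (-0.96), cytotoxic effectors (-0.97), checkpoints (-0.82), regulatory T cells (-0.76), B and plasma cells (-1.76), macrophages (-0.86), dendritic cells (-0.59), mast cells and basophils (-0.62), chemokines (-0.92), the type I interferon (-0.80) and interferon-gamma responses (-0.98), MHC class I (-0.40) and class II presentation (-0.71), NK receptor ligands (-0.31) and the study's key genes (-1.07). Stromal and stress lists were also negative: fibroblast and matrix (-0.66), endothelial (-0.37), skeletal muscle (-2.80), nerve and Schwann cell (-0.59), immediate early (-0.61) and heat shock genes (-0.20). Positive medians were found for hepatocyte and hepatoma genes (0.50), xenobiotic metabolism (0.28), cholesterol biosynthesis (0.27), fatty acid synthesis (0.23), mitotic (0.24), DNA replication (0.21) and ribosomal protein genes (0.10). With an estimated correlation 0 of these 29 lists passed.

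Immune transcripts were higher with GSK343 under control antibody. A lower share of tumor cells would raise the markers of all other cell types alike, but T cell markers rose by 0.8141 more than endothelial markers (0.936 against 0.122, exact permutation p = 0.0159), which argues against that share as the whole cause; exact permutation p for T cell markers against fibroblast (0.545), erythroid (1.24) and keratinocyte genes (1.49) was 0.0556, 0.0556 and 0.183, and macrophage markers rose by 0.603 more than endothelial (0.00794) but were not separated from fibroblast genes (0.334, 0.206). Skeletal muscle in the treated libraries, where Acta1 averaged 197 FPKM, could raise other host transcripts. Yet with the muscle score as a covariate the T cell score was still higher by 0.7299 ± 0.209, against 0.936 ± 0.188 without it. The calls of single genes fell to 3 with muscle and keratinocyte scores together. For Cxcl10 the change shrank and its error grew (from 1.05 ± 0.27 to 0.72 ± 0.30), and the reason over all genes was not tested. What stays open is an effect of the drug itself, for which no mechanism was tested here, and a part that goes with muscle. A lower share of tumor cells as a part of the cause also stays open. Of the list members, 1 of 20 T cell markers and 0 of 23 macrophage markers are held by another list, and no sort or gate removed host cells. Other immune lists share more: 7 of 16 cytotoxic effectors, 12 of 31 interferon-gamma response genes and 13 of 32 chemokines. Calls of those lists are therefore not separate evidence.

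With GSK343 present, 1456 genes differed between the antibodies. A sequencing batch that goes with the antibody would shift the same genes in tumors without GSK343. Across these genes the changes without the drug had a slope of 0.0955 on those with it (jackknife SE 0.132, 0.0178 to 0.156 with 1 library without GSK343 left out). Only 1 gene passed in both, although 941 of the 1456 had the same sign. The SE leaves out the spread of the libraries with GSK343. The genes were chosen by their change in those libraries, which can lower the slope. Within these limits the slope argues against such a batch as the whole cause and leaves a smaller contribution open. The libraries of control antibody plus GSK343 enter both this comparison and the GSK343 comparison under control antibody, so a feature of that group alone would give both results, and the biological difference that the design names, the antibody, stays open as untested.

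Other regroupings of the same libraries were tested, 100 per comparison with the real one included. For GSK343 under control antibody 3 of 100 called as many genes as the real 787, the highest other 1521, and for the average 3 of 100 reached 135, the highest other 499. In both, the share was under 0.05, without adjustment for the number of comparisons. The highest other split called more genes than the real one in each, so these counts alone do not exclude chance. The 499 against 135 is several times the real count and points to a structure of the samples; the split with 1521 placed replicate 1 of control antibody plus GSK343 with the controls. For GSK343 under anti-CXCL10 the real count was 0, which any split reaches by construction (100 of 100), so this count says nothing about chance; the highest other was 596, for replicates 1, 2 and 5 of anti-CXCL10 together with replicates 3 and 5 of anti-CXCL10 plus GSK343, which also points to a structure of the samples. For the remaining comparisons only the real split, always among the 100, reached the real count. These were the interaction (real 9, highest other 1), anti-CXCL10 without GSK343 (real 2, highest other 1) and anti-CXCL10 with GSK343 (real 1456, highest other 669). The count of 1456 argues against chance, whereas 2 against 1 does not decide. The interaction's regroupings exchanged antibody labels within each treatment, so they bear on any antibody difference and not on the interaction alone.

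Single libraries stood far from the rest of their group in 32 of 436 checks, where chance marks about 1 in 20 groups, or 21.8. Among list scores these were chemokines in anti-CXCL10 plus GSK343 replicate 5 (3.53), hypoxia and glycolysis in anti-CXCL10 replicate 5 (5.81), immediate early genes in control antibody plus GSK343 replicate 3 (5.77) and anti-CXCL10 replicate 3 (5.18), and platelet (2.50) and nerve and Schwann cell genes (1.53) in control antibody plus GSK343 replicate 1. Control antibody replicate 3 stood apart in Nos2 (6.17 FPKM), Rps15a (942), Chil3 (14.9), Gzmb (16.0) and Ifng (3.62), replicate 2 in Hdac10 (6.89) and replicate 5 in Fam26f (1.33). With GSK343 added, replicate 3 did so in Ces2e (0.70 FPKM) and Rps15a (656), and replicate 1 in Esm1 (4.16). In anti-CXCL10 tumors Arf2 (7.01 FPKM) and Serpind1 (72.9) in replicate 5, S1pr1 (10.8) in replicate 2 and Ccl11 (7.62) in replicate 4 stood apart. With anti-CXCL10 plus GSK343 the genes were Arf2 (3.97 FPKM), Serpina6 (130), Slc44a3 (13.3), Cd48 (8.53) and Gzmb (6.52) in replicate 5, Eps8 (3) and Lrrc47 (10) in replicate 1, Krt23 (11.8) in replicate 3, Cd69 (2.66) and Rps15a (403) in replicate 4, and Cxcl11 (2.15) in replicate 2.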

How the results depend on the processing

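The settings with scaling, covariates or without the 3 libraries highest in skeletal muscle markers were chosen after the data were seen. No named gene result that passed in the original fit changed sign in any setting. Results that had not passed did: with 1 library left out, Cxcl10 under anti-CXCL10 ranged from -0.188 to 0.114. Cxcl9 ranged from -0.109 to 0.295 there, and Cxcr3 from -0.075 to 0.077. The correlation of the GSK343 effects also changed sign without anti-CXCL10 replicate 2 (-0.013) or 5 (-0.030). Counts of genes for GSK343 under control antibody, under anti-CXCL10 and averaged, the interaction, and anti-CXCL10 without and with GSK343 were 750, 0, 120, 8, 2 and 1381 with a pseudocount of 0.1, and 831, 0, 137, 12, 2 and 1424 with median-ratio scaling; no filter, a filter at 5 FPKM and quantile normalization also stayed within 1.5 times. A log2 change of at least 1 as well left 229, 4 (average) and 219 (anti-CXCL10 with GSK343). Fits of the compared groups alone gave 233 genes for GSK343 under control antibody, where Cxcl10 (1.046) and Cxcl9 (1.345) lost their calls with larger adjusted p, and 1 higher for anti-CXCL10 without GSK343, not among the original 2, which were lower. The cause was not tested.

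With muscle and keratinocyte scores as covariates the counts were 3 (GSK343 under control antibody), 0 (average), 0 (interaction), 0 and 9 (anti-CXCL10 without and with GSK343), with Cxcl10 at 0.716 and Cxcl9 at 0.787 under control antibody and Cxcl10 at -0.456 for anti-CXCL10 with GSK343, none past the threshold. Without the 3 libraries highest in muscle markers, which leaves fewer samples, the counts were 15, 2, 1, 0 and 497 in that order, with 0.992, 0.982 and -0.799 for the same genes, none past the threshold. Of 267 named gene results, 1 kept its call with the covariates, 26 without the 3 libraries, and 260 with median-ratio scaling. Camera with an estimated correlation called 0 lists in each comparison; fry called 0 for GSK343 under anti-CXCL10, 16 for the average, 13 for the interaction and 0 for anti-CXCL10 without GSK343. The correlation of the GSK343 effects was 0.019 over all genes.

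Leaving out 1 library gave 299 to 1389 genes for GSK343 under control antibody, 0 to 1 under anti-CXCL10, 5 to 556 on average, 0 to 476 for the interaction, 0 to 2 for anti-CXCL10 without and 837 to 1829 with GSK343. Lists numbered 7 to 16 under anti-CXCL10 and 4 to 15 for anti-CXCL10 without GSK343, and the correlation ran from -0.030 to 0.359. Cxcl10 ranged from 0.915 to 1.205 under control antibody and from -1.011 to -0.722 for anti-CXCL10 with GSK343. Cxcl9 and Cxcr3 ranged from 1.178 to 1.631 and 0.565 to 0.985 under control antibody, 0.618 to 0.881 and 0.283 to 0.493 on average, -1.501 to -1.048 and -0.983 to -0.563 in the interaction, and -1.118 to -0.665 and -0.875 to -0.455 for anti-CXCL10 with GSK343.

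With the replicate number as a block the interaction called 57 genes, among them the 9 called without it, and anti-CXCL10 without GSK343 0, with Cav1 no longer past the threshold (adjusted p = 0.0831); other counts stayed within 1.5 times. The numbers were not taken to pair the libraries, since only 12 of 27 same-numbered pairs correlated over 0.1 (mean 0.0719, -0.199 to 0.318, other pairs -0.0179). That 8 of 19 libraries correlated best with their own number is a hint from the data, not from the design, so some shared structure is not excluded. Settings that need counts (size factors, count tests, precision weights, filters on CPM) were not run, as the values are FPKM, and unknown depth limits the low genes most.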

Other observations

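The tests of Y-linked transcripts and of nuclear copies were chosen after the results were seen.

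Y-linked transcripts moved with the same groups as the immune lists and the skeletal muscle score, which averaged 1.85 and 4.04 with control antibody without and with GSK343 and 2.31 and 1.88 with anti-CXCL10. Ddx3y, an RNA helicase gene of the Y chromosome, had 3.48 FPKM with control antibody and 6.87 ± 2.30 with GSK343 added (0.78 ± 0.20, adjusted p = 0.031, 5 of 5 treated libraries above the highest control), and 3.74 and 3.09 with anti-CXCL10 without and with the drug. Eif2s3y, a translation initiation factor gene, had 4.98 and 10.3 ± 3.37 FPKM (0.88 ± 0.20, adjusted p = 0.017, 4 of 5), and 5.87 and 5.03. Xist, the transcript of the inactive X chromosome, was present in every group at 99.7 ± 9.49, 85.4 ± 14.7, 78.4 ± 10.8 and 68.2 ± 25.8 FPKM, in the order control antibody, control antibody plus GSK343, anti-CXCL10 and anti-CXCL10 plus GSK343. The mean of both Y-linked genes was higher by 0.83 with GSK343 under control antibody (exact permutation p = 0.0238) and lower by a difference of -0.89 between the antibodies with GSK343 (exact permutation p = 0.00794), and differed by -0.21 with GSK343 under anti-CXCL10 (exact permutation p = 0.127).

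A candidate explanation is that Y-linked transcripts follow the share of male immune cells among tumor cells that carry Xist, with the sex of the mice not given in the labels. The test used the 14 libraries of the other groups, leaving out control antibody plus GSK343, where the Y-linked genes were highest. These 14 include the groups it was compared with above, so they are not independent of the pattern. In them the Y-linked score and the mean of T cell and macrophage scores correlated at r = 0.4282 (permutation p = 0.126, adjusted over 7 relations 0.44). The rank correlation was rho = 0.354 (permutation p = 0.214, adjusted 0.692), and r was 0.105 without the 2 libraries farthest from the median immune score. The test does not decide on the hypothesis, since the coefficient depended on those 2 libraries and did not pass, and muscle or other host cells stay open as sources, untested.

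Skin transcripts varied widely between tumors: the basal keratin Krt14 had 60.1 ± 97.9, 13.5, 10.4 and 19.4 FPKM in the same order of groups, and the keratinocyte list was not past the test for GSK343 under control antibody (median -0.56, camera adjusted p = 0.139), whereas camera called it lower for anti-CXCL10 without GSK343 (median -0.91, adjusted p = 0.851 with an estimated correlation).

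Nuclear gene models that copy mitochondrial genes were among the most abundant rows, and rows of the mitochondrial chromosome numbered 0. Fragments of the mitochondrial genes can hardly be told from these copies by sequence. The values below therefore need not be transcripts of the nuclear models. Gm10925 on chromosome 1 (24613974 to 24614651, build GRCm38), 100% identical to mt-Atp6, had 5942 FPKM on average, rank 2 of all genes. Gm29216 (99.8% identical to mt-Co1), Gm28437 (100% to mt-Co3) and Gm28661 (100% to mt-Co2) had 5093, 3537 and 2138 FPKM, and these 4 models held between 1.80% and 5.75% of a library's summed FPKM. Each had its highest group mean in control antibody plus GSK343 (Gm10925 7531 FPKM, against 5135 to 5969 in the other groups), but the difference from control antibody did not pass for any of the 4 (adjusted p = 0.657, 0.459, 0.473 and 0.595 in the order named).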
